A study of Mus musculus with 12 samples.

How the data were processed

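The data are expression values of 12 arrays of mouse blastocysts in 3 groups of 4: control, 20 pulses and Ca-free medium. Per the labels, total RNA was purified with a PicoPure kit and turned into biotin-labelled cRNA with an Affymetrix labelling assay for small samples. Per the submitters' processing notes the values were made with MAS5, whose version is not given. The deposited table holds 45037 probe sets and 64 array controls as linear intensity with 0 missing values, and every array had been scaled to the same 2% trimmed mean (150.001), without log transformation or quantile normalization. Detection calls, scan dates and raw image files were not used here, and the number of arrays limits the precision. The labels do not say whether replicates are separate collections of embryos, so the p-values measure only the spread between these samples.

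Each array was scaled to a 2% trimmed mean of 500, which multiplies all deposited values by 3.33, and 32 was added before taking log2. Probe sets with a mean signal of at least 100 over the 12 arrays were tested, which left 27808; on the deposited scale the added value is 9.60 and the minimum 30.0. Signals in the text are on the rescaled intensity scale unless called deposited. A table of the platform's probes paired 34958 probe sets with a single gene, 932 with several and 9211 with none. Of the symbols, 34754 were matched through gene identifiers to a RefSeq annotation (GRCm38.p6) used for names only. The build behind the platform's table is not given in the sources used here, and no coordinates are printed.

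Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, all 12 arrays in a single model), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, with the brightest tested probe set of each gene. All 36 lists fixed in advance had at least 5 measured genes. They cover lineages and functions of the blastocyst, housekeeping functions, stress responses and markers of other cell types. Members past the threshold were counted both over all probe sets and adjusted over the list alone, and camera was repeated with an estimated correlation. Array controls (3' and 5' probe sets of Actb and Gapdh, 18S rRNA, 9 hybridization control and 27 bacterial control probe sets) were compared with exact two-sided permutation tests. Residuals of arrays of different groups correlated little (mean r 0.0156 for same replicate numbers and -0.00521 for other numbers). Still, 7 of the 12 arrays correlated best with an array of their own number, so pairing is not excluded. The main model used no pairing, and a block for replicate number was an alternative.

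Genes are named by a rule. For each treatment against control it takes the 8 largest increases and 8 largest decreases among probe sets that passed, are paired with a single gene, have every treated array on the same side of every control array and a mean signal of at least 200 in the higher group. It adds the 3 members with the smallest p of every list that passed, in the list's direction, and the lineage markers Pou5f1, Nanog, Cdx2, Eomes, Gata4, Gata6 and Krt8 whatever their test. For Ca-free medium against 20 pulses it takes the 5 largest each way. The groups, tests, gene lists, this rule and the first set of alternatives were chosen before the data were examined.

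Alternatives tried were quantile normalization, the values as deposited, median scaling, added values of 1 and 100, no filter and a minimum of 300. Also tried were no intensity trend, array weights, models of only the 8 arrays compared, a block for replicate number, stricter thresholds, each array left out in turn, the mean of a gene's probe sets, and controls divided between the treatments. Chosen after the data were seen were scaling to the hybridization controls, fits with only controls 1 and 2, controls 3 and 4, Ca-free arrays 1 and 4 or Ca-free arrays 2 and 3. The same holds for the count of calls common to several scalings, calls from pairs of controls checked on the other controls, and 10000 random gene lists matched to each list in size and signal (40 signal bins).

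The procedure was tested on simulated data. For Ca-free medium against control, 40.3%, 88.1% and 100% of probe sets changed by 1.5, 2 and 3 times were recovered among 27808, with 5 false calls. For 20 pulses against control, a simulated list was found (adjusted p = 4.74e-10) and 0 of the 36 real lists were called on the same simulated arrays by camera in limma. The simulated noise was independent between probe sets, without correlation between genes, pairs of control arrays or shifts that depend on signal. The simulation therefore does not show how often false calls or false lists arise on the real arrays.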

Results

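Gene expression was measured in mouse blastocysts, embryos with an inner cell mass and an outer trophectoderm, on 12 arrays with 45037 probe sets besides the array controls. Per the labels, 4 arrays carried RNA of control blastocysts, 4 of blastocysts treated by 20 pulses and 4 of blastocysts cultured in Ca-free medium. The study's title places the pattern of Ca2+ oscillations in the fertilised egg, so the comparisons ask which genes differed in the blastocyst after the Ca2+ signal had been altered. The form of a pulse and the time spent in Ca-free medium are not given in the sources used here. The deposited median signal lay between 49.4 and 53.05 on the control arrays, between 47.4 and 53.7 after 20 pulses and between 38.3 and 39.2 in Ca-free medium, while the 2% trimmed mean of every array was 150.001. In all, 27808 probe sets of 13599 genes with a mean signal of at least 100 were tested.

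The Ca-free arrays stood apart from the others on the first principal component, which held 40.2% of the variance. Across genes, which are not independent replicates, the mean Pearson correlation was 0.976 between control arrays, 0.961 between control and Ca-free arrays and 0.972 between control arrays and those of 20 pulses. The controls fell into pairs. The ratio of the 3' to the 5' probe set of Actb was 1.59 and 1.67 in controls 1 and 2, and 2.69 and 2.64 in controls 3 and 4. The 5' probe set of 18S rRNA read 2409 and 2559 in the first pair and 878 and 883 in the second. Ca-free arrays 1 and 4 likewise lay apart from arrays 2 and 3 on the third component, which held 9.89% of the variance. The labels give no batch or date for either split.

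**Figure D1:**
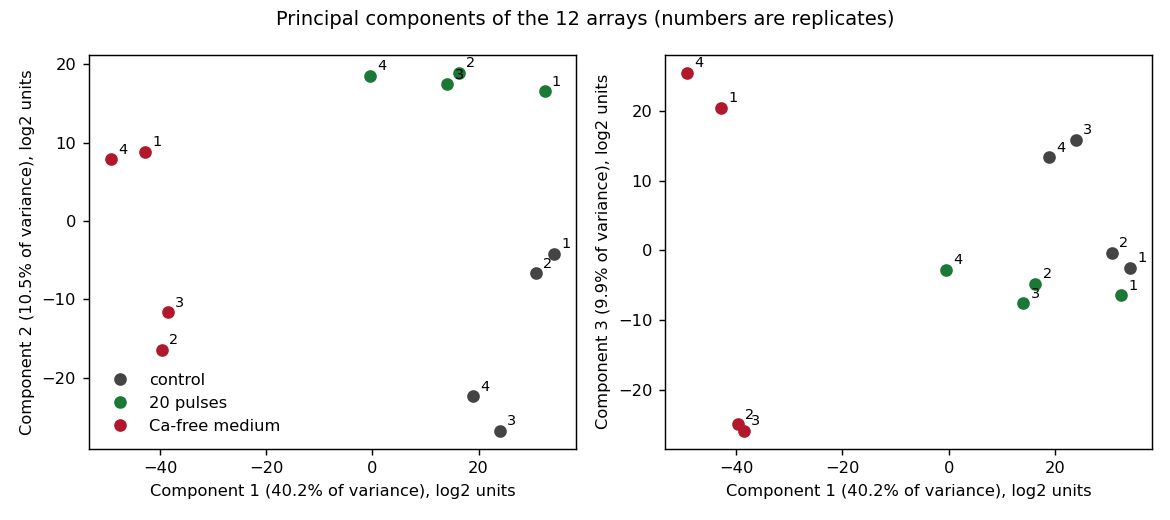
Scores of the 12 arrays on the first principal components, with numbers for the replicates and the share of variance on each axis (40.2% and 10.5% for the first pair of axes). The 4 Ca-free arrays lie at -49.3 to -38.5 on the first component and the other 8 at -0.499 to 34.2.

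Against control, blastocysts from Ca-free medium had more mRNA signal for Chd4, a chromatin remodeller of the NuRD complex, and less for Arl14, a small GTPase, and for Eomes, a transcription factor of the trophectoderm. Chd4 read 406 ± 39.2 in Ca-free medium and 52.9 ± 7.62 in control (SD, n = 4 each; log2 change 2.37, adjusted p = 1.38e-04), and another probe set of the gene rose by 1.03. Arl14 read 80.6 ± 24.3 against 338 ± 26.2 (log2 change -1.74, adjusted p = 5.87e-05). Eomes read 2284 ± 194 against 3725 ± 301 (log2 change -0.70, adjusted p = 5.45e-04), while its other probe set did not pass the test (log2 change -0.20). These 3 genes passed in the same direction under all 4 scalings of the arrays. The other large increases by the rule for named genes were in Enah, an actin regulator (log2 change 2.20), Ltn1, a ubiquitin ligase of ribosome quality control (2.09), and Uck2, a uridine-cytidine kinase (2.08). They were followed by Sart3, a splicing factor (1.99), Zmynd19 (1.87), Coa3, an assembly factor of cytochrome c oxidase (1.83), and Pms2, a mismatch repair protein (1.82). A further probe set was called higher too in Chd4 (1 of 2 others), Enah (1 of 4), Ltn1 (1 of 3), Zmynd19 (1 of 2) and Coa3 (1 of 1). The remaining probe sets of these genes were not called. In Sart3 and Pms2 a further probe set was called lower, and the other 4 probe sets of Uck2 were not called higher. The other large decreases were in Hspa1a, a stress-inducible chaperone (log2 change -2.73), the keratin Krt72 (-1.69), 4930447F24Rik (-1.67), the flagellar protein Cfap61 (-1.65), the germline RNA-binding protein Boll (-1.61), the sulfotransferase Ust (-1.53) and Adamtsl3 (-1.52).

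Some of these genes differed between the pairs of control arrays. Hspa1a read 5717 and 5219 in controls 1 and 2, 260.3 and 283.6 in controls 3 and 4, and 173 ± 73.1 in Ca-free medium (SD, n = 4). After 20 pulses Hspa1a read 140 to 185, also below every control array, so its lower signal was not particular to Ca-free medium. The call of Hspa1a in Ca-free medium ended against controls 3 and 4 only, where the log2 change was -0.64. It also ended with Ca-free arrays 1 and 4 only, at a change of -2.27. Enah read 231 and 228 in controls 1 and 2, and 28.0 and 34.7 in controls 3 and 4. Sart3 read 108 and 98.3 in the first pair and 39.3 and 31.7 in the second, and the other called probe set of Chd4 620 and 631, and 412 and 407. These 3 probe sets were called against either pair. The calls of Uck2 (1.86), Ust (-1.51) and Adamtsl3 (-1.34) ended against controls 3 and 4 only as well, with smaller shifts of the change. The call of Adamtsl3 also ended under quantile normalization (-1.23) and with Ca-free arrays 2 and 3 only (-0.79). Ust did not follow the pairs, at 508 and 535 in controls 1 and 3, and 117 and 103 in controls 2 and 4. Its call ended under quantile normalization (-1.27) and median scaling (-1.22), and with Ca-free arrays 1 and 4 only (-1.58) or 2 and 3 only (-1.47). It ended without control 1 or without control 3 too (log2 changes from -1.88 to -1.19 with any of the 8 arrays left out).

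**Figure D2:**
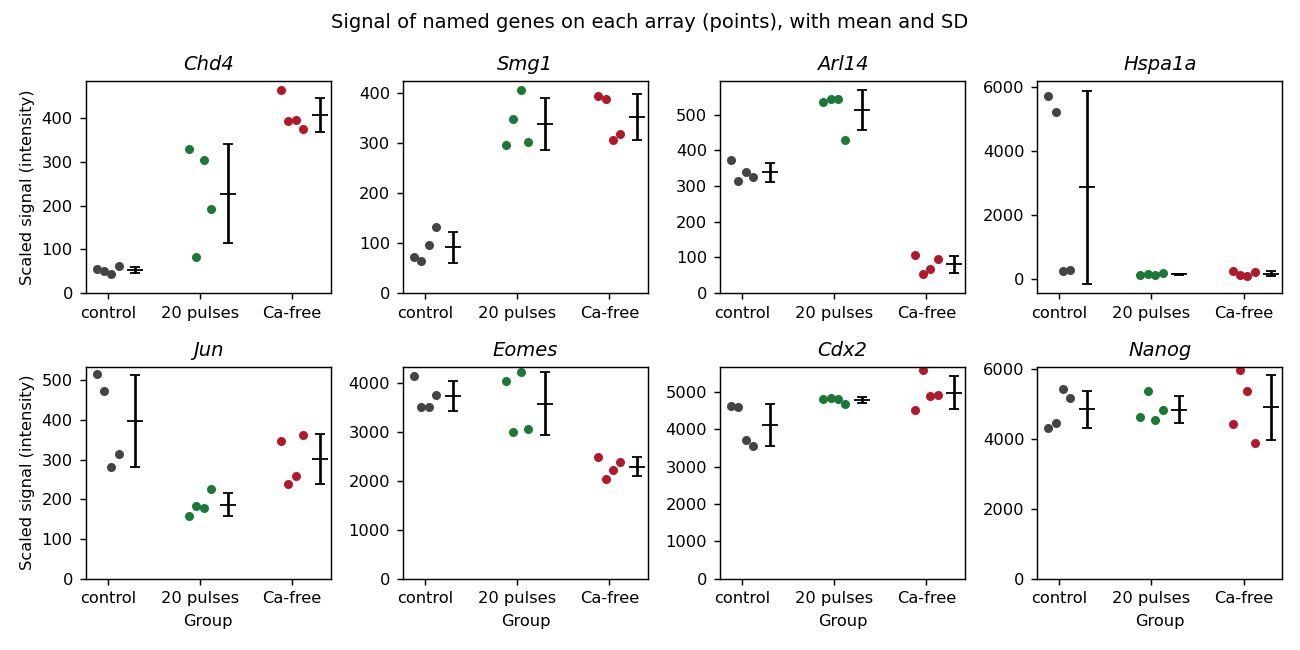
Signal of 8 named genes on each array, with the mean and SD of each group of 4 (linear axis, intensity). Chd4 rises from a mean of 52.9 in control to 406 in Ca-free medium, Arl14 falls from 338 to 80.6, and Hspa1a reads 5717 and 5219 in controls 1 and 2 and 260.3 and 283.6 in the other controls.

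Among the lineage markers of the blastocyst, Gata4, a primitive endoderm factor, read 127 ± 22.1 in Ca-free medium and 222 ± 31.99 in control (SD, n = 4; log2 change -0.69, adjusted p = 0.00238). Its call ended under quantile normalization and median scaling. Cdx2, the trophectoderm factor, read 4981 ± 437 against 4123 ± 571 (log2 change 0.28, adjusted p = 0.0199), and Pou5f1, the pluripotency factor, 5952 ± 507 against 5173 ± 440.4 (0.20, adjusted p = 0.0329). Both calls ended under quantile normalization and when the arrays were scaled to their hybridization controls, where Cdx2 was at 0.07 and Pou5f1 turned to -0.00434. The Cdx2 call also ended without control 3, control 4 or Ca-free array 2 (0.21 to 0.33 over the arrays left out). The Pou5f1 call ended without control 1, control 2, Ca-free array 1 or Ca-free array 4 (0.16 to 0.25), without the intensity trend and in a model of only the 8 arrays compared. Cdx2 was not called against controls 1 and 2 only (0.11) or with Ca-free arrays 1 and 4 only (0.20), and Pou5f1 was not called against controls 3 and 4 only (0.10) or with Ca-free arrays 2 and 3 only (0.10). Nanog (0.01), Gata6 (0.05) and the keratin Krt8 (0.01) did not pass. All 3 passed as higher under median scaling (0.42, 0.46 and 0.42), and all 3 turned negative with hybridization control scaling (-0.20, -0.15 and -0.20), where Krt8 passed as lower.

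By limma, 11193 of the 27808 probe sets passed, 2944 higher and 8249 lower in Ca-free medium. The median change of all probe sets was -0.18 on the log2 scale. The split followed the scaling, with 2738 higher and 2760 lower under quantile normalization, 10257 and 1515 under median scaling, and 768 and 13773 with hybridization control scaling. The change also followed the signal, with a median of -0.39 in the second lowest of 10 equal sets by signal and of 0.12 in the highest. Called the same way under the trimmed mean, quantile and median scalings were 1792 probe sets higher and 1238 lower, from 1461 and 845 genes. With hybridization control scaling as well, these numbers were 762 and 1238.

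**Figure D3:**
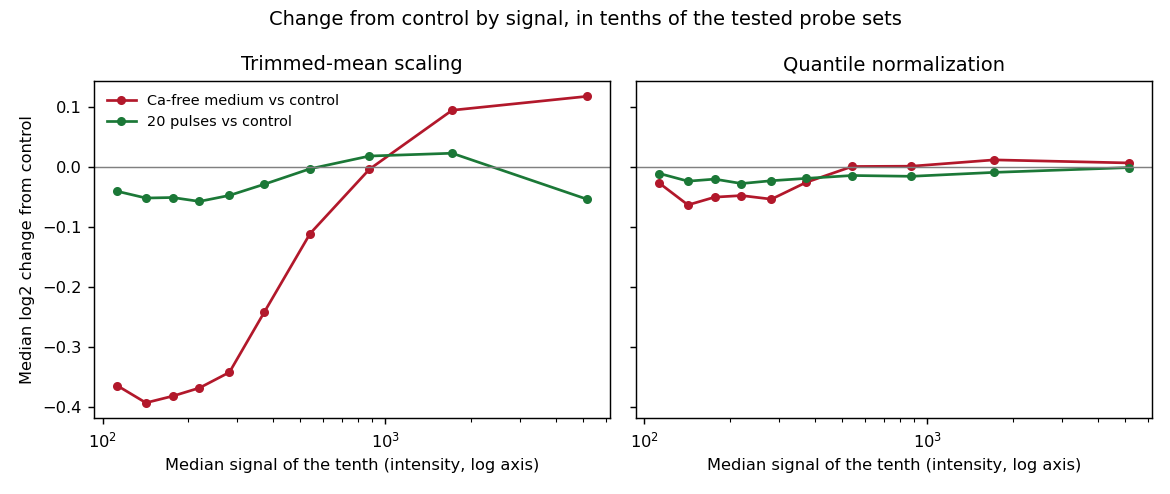
Median log2 change from control in 10 equal sets of the tested probe sets ordered by mean signal (log axis, intensity), for Ca-free medium and for 20 pulses. In Ca-free medium the medians run from -0.39 in the second lowest set to 0.12 in the highest with trimmed mean scaling, and from -0.06 to 0.01 after quantile normalization.

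Gene lists rose together in Ca-free medium relative to all genes, whose median change was -0.13. Of 76 measured mitochondrial ribosomal protein genes, 38 rose and 3 fell (41 and 3 adjusted over the list alone), with a list median of 0.20 (adjusted p = 7.03e-13 by camera in limma; adjusted p = 0.278 with an estimated correlation). Examples are Mrpl33 (log2 change 1.03), Mrpl18 (0.48) and Mrpl47 (0.47). Of 77 genes of RNA polymerase II transcription, 31 rose and 3 fell (32 and 5 adjusted over the list alone), with a median of 0.16 (adjusted p = 7.82e-08; adjusted p = 0.107 with an estimated correlation). They include Polr2a, the largest subunit (0.49), the Mediator subunit Med29 (0.76) and Gtf2e2 (0.32). Of 44 cytosolic ribosomal protein genes, 12 rose and 1 fell (3 and 0 adjusted over the list alone), with a median of 0.10 (adjusted p = 1.49e-06; adjusted p = 0.423 with an estimated correlation). They include Rps2 (0.50), Rpl37a (0.31) and Rpl35 (0.22). These 3 lists also passed under quantile normalization, with medians of 0.10, 0.09 and 0.03. However, all 3 medians lay below 0 with hybridization control scaling (-0.00448, -0.04 and -0.11). Against 10000 random lists of the same size and signal for each, the medians of these 3 lists stood at percentiles 99.93, 99.98 and 85.45. The rise of the cytosolic ribosomal proteins was therefore not told apart from that of equally bright genes.

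Further probe sets of Mrpl33 and Mrpl47 were called lower, and of the other 5 of Rpl35, 3 were called higher and 1 lower. Another 11 lists rose and passed with the preset correlation (adjusted p = 1.03e-09 to 0.0107), none of them under quantile normalization, and all had medians below 0 with hybridization control scaling. In oxidative phosphorylation 31 of 89 genes rose and 4 fell (32 and 5 adjusted over the list alone), with Ndufaf4 (0.52), Ndufa6 (0.51) and Uqcrc2 (0.30) as examples (adjusted p = 0.307 with an estimated correlation). Among proteasome subunits 15 of 36 rose and 0 fell by limma (15 and 0 adjusted over the list alone), such as Psmb7 and Psmb1 (0.41 each) and Psma7 (0.38) (adjusted p = 0.278 with an estimated correlation). In ribosome biogenesis 22 of 59 rose and 2 fell (25 and 2 adjusted over the list alone), such as Nop56 (0.39), Pes1 (0.35) and Wdr75 (0.34) (adjusted p = 0.107 with an estimated correlation). In cell cycle and mitosis 15 of 54 rose and 4 fell (15 and 4 adjusted over the list alone), such as the kinetochore motor Cenpe (0.83), Ube2c (0.47) and the kinase Nek2 (0.45) (adjusted p = 0.173 with an estimated correlation). In the cytoskeleton list 11 of 34 rose and 2 fell (11 and 2 adjusted over the list alone), such as the tropomyosin Tpm1 (0.59), Arpc5 (0.27) and Rhoa (0.22) (adjusted p = 0.246 with an estimated correlation). In splicing, whose median was 0.06 but -0.04 under quantile normalization, 19 of 70 rose and 7 fell (17 and 5 adjusted over the list alone), such as Srsf5 (0.48), Srsf9 (0.40) and Srrm2 (0.34) (adjusted p = 0.152 with an estimated correlation). Translation factors (11 of 43 rose, 2 fell; 9 and 2 adjusted over the list alone) included the release factor Etf1 (0.60), Gspt1 (0.31) and Eif3h (0.26) (adjusted p = 0.307 with an estimated correlation). The chromatin list (9 of 45 rose, 4 fell; 9 and 3 adjusted over the list alone) included the DNA methyltransferase Dnmt3a (0.81) and the Polycomb protein Suz12 (0.46) (adjusted p = 0.152 with an estimated correlation).

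Among antioxidant genes 8 of 23 rose and 2 fell (9 and 2 adjusted over the list alone), such as Gclm (0.48), Gpx4 (0.39) and Prdx2 (0.35) (adjusted p = 0.246 with an estimated correlation). In the tRNA synthetase list, which includes the accessory protein Aimp1, 6 of 21 rose and 1 fell (6 and 1 adjusted over the list alone). Examples are Hars (0.48), Eprs (0.35) and Aimp1 (0.29), and the list had an adjusted p = 0.307 by camera with an estimated correlation. Among vesicle and lysosome genes 7 of 30 rose and 3 fell (7 and 3 adjusted over the list alone), such as Atp6v1b2 (0.68), Atp6v1a (0.34) and Gla (0.34) (adjusted p = 0.307 with an estimated correlation). Psmb1, Nek2, Atp6v1b2 and Gla each have a further probe set that was called lower, and Gspt1 and Tpm1 each have 1 called lower and 1 called higher. The calls of Aimp1 and Gspt1 ended under quantile normalization, and that of Eif3h with Ca-free arrays 2 and 3 only (0.21). With hybridization control scaling the calls of more of the raised members named above ended, at log2 changes of 0.00998 (Rpl35) to 0.19 (Nop56). The others were Gtf2e2, Rpl37a, Uqcrc2, Pes1, Wdr75, Arpc5, Rhoa, Srrm2, Gspt1, Eif3h, Gpx4, Prdx2, Eprs, Aimp1, Atp6v1a and Gla. Markers of oviduct and uterine epithelium, another tissue, were the list that fell. Of 10 measured, 6 fell and 0 rose by limma (8 and 0 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.0103; adjusted p = 0.152 with an estimated correlation). Examples are the progesterone receptor Pgr (-0.84), the oviduct glycoprotein Ovgp1 (-0.78) and Krt5 (-0.73). Under median scaling the call of Krt5 ended (-0.35) and Ovgp1 was at -0.42. This list did not pass under quantile normalization or with hybridization control scaling. The signal of these markers was low, 159.7 ± 15.7 for Ovgp1 in Ca-free medium and 297 ± 37.6 in control (SD, n = 4). Lists for the epiblast, trophectoderm and primitive endoderm did not pass (adjusted p = 0.127, 0.932 and 0.994).

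**Figure D4:**
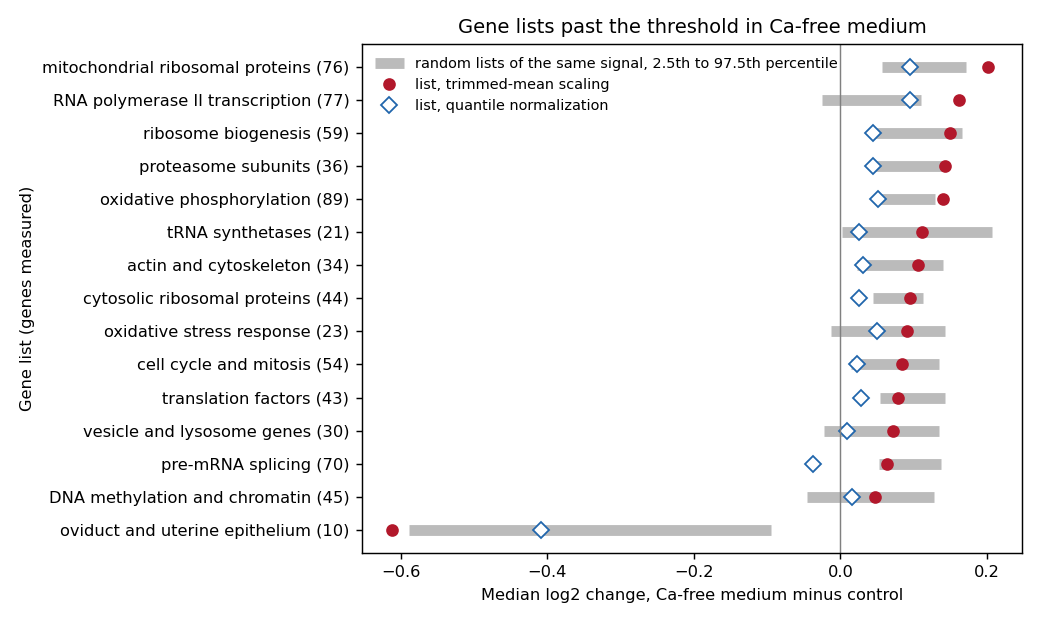
Median log2 change of the gene lists that passed in Ca-free medium against control, beside their medians after quantile normalization. Mitochondrial ribosomal proteins stand at 0.20 and oviduct and uterine epithelium at -0.61; splicing turns from 0.06 to -0.04 after quantile normalization, and with hybridization control scaling (not drawn) all these medians lie below 0.

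Control probe sets moved with the Ca-free group as well. The mean log2 ratio of the 3' to the 5' probe sets of Actb and Gapdh was lower than in control (difference -0.54, exact two-sided permutation p = 0.0286, the smallest that 70 arrangements can give, n = 4 each). Alone, Gapdh differed by -0.88 (exact p = 0.0286) and Actb by -0.20 (exact p = 0.429). Signal of the 18S rRNA probe sets was 3.29, 1.49 and 2.14 times that of control at the 5' end, the middle and the 3' end (exact p = 0.0286 each). Hybridization controls were higher by 0.21 on the log2 scale (exact p = 0.0286).

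After 20 pulses, blastocysts had more signal than control for a probe set of Smg1, a kinase of nonsense-mediated mRNA decay. It read 339 ± 51.4 against 91.5 ± 30.7 (SD, n = 4 each; log2 change 1.61, adjusted p = 0.00149). Sart3 rose by 1.74 on the log2 scale, the cadherin Cdh2 by 1.68, the choline kinase Chka by 1.56 and the basement membrane protein Nid1 by 1.55. Chd4 rose by 1.48, the dynein regulator Ndel1 by 1.44 and the splicing regulator Rbm5 by 1.43. Lower were Smim38 (-1.29), Tm4sf4 (-1.26), the telomere helicase Rtel1 (-1.20), Mpped1 (-1.11), the protease inhibitor Serpina3i (-1.11), Gsdmcl1 (-1.02), the transcription factor Jun (-0.94) and Cnnm4 (-0.83). Jun read 186 ± 28.9 after 20 pulses and 396 ± 116 in control (SD, n = 4; adjusted p = 0.0243). These 16 genes passed under all 4 scalings. The other 2 probe sets of Smg1 read 1176 and 963 in control and 1295 and 1062 after 20 pulses. No further probe set of Sart3, Cdh2, Nid1 or Ndel1 passed, whereas 1 of Chka, 1 of Chd4 and 2 of Rbm5 did. Of the genes that fell, Smim38 had a further called probe set, and Rtel1, Jun and Cnnm4 had others that were not called.

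Of the 18 named genes called after 20 pulses, 7 passed with any of the 8 arrays left out. They were Smg1 (1.497 to 1.76), Sart3 (1.54 to 1.92), Cdh2 (1.53 to 2.00), Nid1 (1.34 to 1.70), Ndel1 (1.18 to 1.56), Smim38 (-1.46 to -1.15) and Tm4sf4 (-1.38 to -1.11). The call of Chd4 ended without pulses array 3 or control 3 (1.28 to 1.83 over the arrays left out), and that of Mpped1 without pulses array 4 or control 3 (-1.26 to -0.92). Gsdmcl1 lost its call without pulses array 4, control 3 or control 4 (-1.13 to -0.84), and Cnnm4 without pulses arrays 3 or 4 or controls 3 or 4 (-0.96 to -0.71). Jun lost it without pulses arrays 1, 2 or 3 or control 2 (-1.08 to -0.81). Rtel1 lost it without any of pulses arrays 1, 3 and 4 and controls 2 and 3 (-1.41 to -1.07), and Rbm5 without any of the 4 pulses arrays and controls 3 and 4 (1.14 to 1.60). Serpina3i lost it without any of pulses arrays 2, 3 and 4 and controls 2, 3 and 4 (-1.26 to -0.96), and Chka without any array but control 1 (1.41 to 1.86). Against controls 1 and 2 only, Chd4 (1.48), Chka (1.28), Rbm5 (1.04), Smim38 (-1.26), Serpina3i (-0.95), Mpped1 (-0.92), Gsdmcl1 (-0.83) and Cnnm4 (-0.49) did not pass. Against controls 3 and 4 only, Rtel1 (-0.87) and Jun (-0.60) did not. Eif2a and Tra2a passed against neither pair. Without the intensity trend the calls of Chka, Cnnm4, Jun, Rtel1, Rbm5, Serpina3i, Eif2a and Tra2a ended, and without the filter those of Chka, Gsdmcl1, Rbm5, Serpina3i, Eif2a and Tra2a.

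None of the lineage markers passed after 20 pulses: Pou5f1 (-0.03), Nanog (0.00), Cdx2 (0.22), Eomes (-0.07), Gata4 (-0.31), Gata6 (-0.01) and Krt8 (-0.07), although Cdx2 did with hybridization control scaling (0.39). That scaling turned the signs of Pou5f1, Eomes, Gata6 and Krt8 to positive without a call. By limma, 411 of the 27808 probe sets passed, 307 higher and 104 lower. The split was 369 and 133 under quantile normalization, 308 and 43 under median scaling, and 2125 and 35 with hybridization control scaling, and 260 and 42 passed in the same direction under the first 3 scalings. The median change was -0.03. The count moved with single arrays, to 110.0 without pulses array 4, 111 without pulses array 3, 117 without control 3, 152 without pulses array 2, 215 without control 4 and 256 without control 2. It was 201 against controls 1 and 2 only and 786 against controls 3 and 4 only.

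Lists that passed after 20 pulses were lower, with small medians, and none of the 5 passed with an estimated correlation (adjusted p = 0.468 to 0.554 with an estimated correlation). Over all probe sets, 4391 had an unadjusted p under 0.05 in this comparison. By limma, 0 of 44 cytosolic ribosomal protein genes were called, and 0 adjusted over the list alone (median -0.13). Of 22 heat shock proteins 0 were called, and 4 fell adjusted over the list alone (median -0.12). Of 43 translation factors 1 fell, and 5 fell and 1 rose adjusted over the list alone (median -0.10). Of 36 proteasome subunits 0 were called, and 0 adjusted over the list alone (median -0.09). Of 70 splicing genes 1 fell, and 11 fell and 2 rose adjusted over the list alone (median -0.09). None of the 5 passed under quantile normalization, and all 5 medians turned positive with hybridization control scaling (0.03 to 0.08). Called members were the initiation factor Eif2a (-0.34) and the splicing regulator Tra2a (-0.30), and both calls ended under median scaling, that of Tra2a under quantile normalization too (-0.22). Both ended with hybridization control scaling (-0.18 and -0.14). Eif2a lost its call without any of the 8 arrays (-0.37 to -0.30), and Tra2a without pulses arrays 2 or 4 or controls 2, 3 or 4 (-0.33 to -0.26). The 5' probe set of 18S rRNA read 2.11 times control after 20 pulses (exact permutation p = 0.0286, n = 4 each), but the middle and the 3' end read 0.989 and 1.18 times control (exact p = 0.743 and 0.0857). The size of the 5' difference depended on the control pair. The 5' signal was 2653 to 3688 after 20 pulses, 2409 and 2559 in controls 1 and 2, and 878 and 883 in controls 3 and 4. The difference in the mean log2 ratio of 3' to 5' probe sets of Actb and Gapdh did not pass the same test (-0.29, exact p = 0.2). Alone, Actb differed by -0.42 (exact permutation p = 0.0857) and Gapdh by -0.15 (exact permutation p = 0.429). The Actb ratio was 1.49 to 1.69 after 20 pulses, 1.59 and 1.67 in controls 1 and 2, and 2.69 and 2.64 in controls 3 and 4.

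The direct comparison of the treatments asks how blastocysts from Ca-free medium differed from those given 20 pulses. Arl14 was lowest relative to 20 pulses, at 80.6 ± 24.3 against 513 ± 56.0 (SD, n = 4 each; log2 change -2.29, adjusted p = 3.34e-06). The gasdermin Gsdma2 (-2.04), Cfap61 (-1.62), the gastrokine Gkn3 (-1.61) and Boll (-1.60) were lower too. Coa3 (1.66), Phrf1 (1.60), AW551984 (1.502), the nucleotidase Nt5c3b (1.42) and Sypl (1.31) were higher in Ca-free medium, although a further probe set of AW551984 was called lower. All 10 genes passed under the 4 scalings and with any array left out. By limma, 9070 probe sets passed, 2565 higher and 6505 lower, around a median change of -0.17 over all probe sets. The split was 1415 and 1386 under quantile normalization, 8768 and 978 under median scaling, and 92 and 19868 with hybridization control scaling. In the same direction under the first 3 scalings were 1039 higher and 641 lower.

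In this comparison 16 lists rose and 2 fell relative to all genes, whose median was -0.12. Of these 18, 2 passed with an estimated correlation. The change of probe sets followed the signal here too. Its median was -0.34 in the second lowest of 10 equal sets by signal and 0.17 in the highest. Against 10000 random lists of the same size and signal, 5 of the 16 raised lists stood above the high percentile set as the bound. Of the 2 lists that fell, 0 stood below the matching low percentile. These falls, and the rises of the lists within the bound, were therefore not told apart from those of equally bright genes. Of 44 cytosolic ribosomal protein genes 38 rose and 1 fell (38 and 1 adjusted over the list alone; median 0.23; adjusted p = 0.161 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes 34 rose and 1 fell (38 and 1 adjusted over the list alone; median 0.22; adjusted p = 0.161 with an estimated correlation). Ribosome biogenesis (30 of 59 rose, 1 fell; 33 and 1 adjusted over the list alone) and splicing (30 of 70 rose, 5 fell; 32 and 5 adjusted over the list alone) were the lists that passed with an estimated correlation (adjusted p = 0.0220 each). Growth factors and receptors of the embryo fell, with 12 of 36 genes lower and 2 higher (13 and 2 adjusted over the list alone; median -0.27; adjusted p = 0.114 with an estimated correlation), a list that did not pass under quantile normalization and had a median of 0.07 under median scaling. Medians of the raised lists were below 0 with hybridization control scaling (-0.13 for cytosolic and -0.15 for mitochondrial ribosomal proteins). Relative to 20 pulses, 18S rRNA signal in Ca-free medium was 1.56, 1.51 and 1.81 times at the 5' end, the middle and the 3' end. Hybridization controls were higher by 0.37 on the log2 scale. The log2 ratio of 3' to 5' probe sets differed by -0.73 for Gapdh and 0.22 for Actb (exact permutation p = 0.0286 for each of these values).

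Some probe sets moved the same way under both treatments. Of 245 probe sets called in both comparisons, 186 rose in both, 47 fell in both and 12 moved in opposite directions, so that 233 moved the same way, where independent lists of these sizes, a number that leaves out the shared controls, would share 63.4. Because both comparisons use the same controls, the correlation of the changes across probe sets (Pearson r = 0.506, across genes) was close to that of simulated unchanged groups (0.5004). The covariance was 0.0462 against 0.0134. The simulated unchanged groups shared 0 calls by limma, which sets no expected number because few calls are expected where nothing changed. At an unadjusted p under 0.05 there were 13975 and 4391 probe sets in the real comparisons. With separate controls for each treatment, the shared calls numbered 221, 76, 16, 14 and 6 in 5 of the 6 ways to divide them, where independent lists would share 124, 24.0, 1.98, 1.82 and 0.934. In the other way 20 pulses had 0 calls to share. The correlation r lay from 0.13 to 0.36. The control pairs stayed apart only where Ca-free medium had controls 1 and 2 (r = 0.13) or controls 3 and 4 (r = 0.31). In the other ways each treatment had 1 control of each pair, so a difference between the pairs stayed shared. Probe sets of Sart3 (1.99 in Ca-free medium and 1.74 after 20 pulses), Smg1 (1.66 and 1.61), Nid1 (1.49 and 1.55), Chd4 (2.37 and 1.48) and Cdh2 (1.20 and 1.68) rose in both. Of these genes only Chd4 had a second probe set that rose in both (1.03 and 0.77). Another probe set of Sart3 was called lower in Ca-free medium.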

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

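The tests on bacterial and hybridization controls were chosen after the direction of change in Ca-free medium was seen, the tests on random lists of the same signal and on pairs of controls after those patterns were seen, and the reference from other pairings of the controls after the share of 32.3% was seen; the counts of other splits were planned.

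In Ca-free medium more probe sets were lower (8249) than higher (2944) with trimmed mean scaling. Of 35 splits of the 8 arrays only 1, the real one, called as many as 11193, and the highest other called 37. This is the smallest share that 35 splits can give. Other splits mix the groups, which adds the group difference to the spread and lowers their counts. The splits argue against chance division but do not exclude it. The 27 bacterial control probe sets match no mouse transcript and read at most 209.6 on any array. Their median log2 change was -0.223, with all 4 Ca-free arrays below all 4 controls (exact permutation p = 0.0286, n = 4). It was -0.223 too in 22462 other dim probe sets with signals of 2.48 to 155.8, a range that reaches below the minimum for testing. At such signals the scaling or background of the arrays may account for the lower values. Tested probe sets changed more, with medians of -0.39 to -0.34 in the lowest 5 of 10 equal sets by signal. The equal medians therefore do not show that scaling or background accounts for the 8249 lower calls. The hybridization controls, added after labelling, were higher by 0.207 in Ca-free medium, but as every array had been deposited at the same trimmed mean, the scaling itself moves these controls and the value does not separate lower transcript levels in the embryo from a lower background. A true fall in many transcripts after culture in Ca-free medium therefore stays open and untested.

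The lists that rose in Ca-free medium hold bright genes, and bright probe sets rose as a whole. Against 10000 random lists of the same size and signal, the median of the mitochondrial ribosomal proteins stood at percentile 99.93 and that of RNA polymerase II transcription at 99.98, above the bound set beforehand, which argues against signal alone for these lists. Of the other 12 raised lists, 2 stood above that bound (oxidative phosphorylation at 99.59 and proteasome subunits at 97.98), so for the 12 as a set signal and treatment cannot be told apart. An effect of Ca-free culture on the first lists is a hypothesis that could be followed up, although none of the 15 lists passed with an estimated correlation (adjusted p = 0.107 to 0.423). The lower 3' to 5' ratio and the higher 18S rRNA signal of the same arrays were not tested as sources of these rises.

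After 20 pulses 411 probe sets were called. Only 1 of 35 splits, the real one, gave as many, and 14 was the highest other count. For Ca-free medium against 20 pulses it was also 1 of 35, with 9070 called and 4 as the highest other. These shares are again the smallest that 35 splits can give, so they argue against chance division without excluding it. Of the 411, 407 (99.03%) kept at least 50% of their change against each of the control pairs 1 and 2, and 3 and 4; this passed the bound that had been set beforehand against a difference between the pairs, but the calls were made from these same 4 controls, which selects probe sets that differ from both pairs, so the share decides nothing. Of 786 probe sets called against controls 3 and 4 only, 85.6% kept their direction and 32.3% at least 50% of their change against controls 1 and 2, and of the 201 called the other way 89.1% and 52.2%. The share of 32.3% met the bound set before its value was known for a difference between the control pairs (under 50%). The rule was narrowed after that value was seen, to ask for a reference from other pairings with a like number of calls. The other pairings of the controls kept 80.6% to 94.4% but called only 18 to 88 probe sets, so they are no reference. By the later rule, for the calls against a single pair, a difference between the control pairs cannot be told apart from an effect of the pulses. An effect of the pulses stays open, and no biological difference between the control pairs was tested, since the labels give none.

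The 18S rRNA probe sets, which no comparison of genes used, read 3.29, 1.49 and 2.14 times control in Ca-free medium at the 5' end, the middle and the 3' end. In 282 groups of 4 arrays, 10 had an array far from the other 3, where chance gives about 14.1. Uck2 read 375 in control 3 and 180.2 to 186 in the other controls. Cdh2 read 145 in control 4 and 34.7 to 50.1 in the others. Etf1 read 3793 in control 3 against 3169 to 3268. After 20 pulses, Arl14 read 429 in array 4 and 534 to 544 in the others. Ust read 555 in array 2 of that group against 111 to 152, and Rtel1 263 in the same array against 142 to 157. Array 1 of the group read 3451 for Aimp1 against 3692 to 3718, and 125 for AW551984 against 42.3 to 55.3. In Ca-free medium, Krt72 read 116 in array 2 against 31.9 to 45.4, and Srrm2 6334 in array 3 against 6826 to 6921.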

How the results depend on the processing

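The alternatives with scaling to hybridization controls and with only some control or Ca-free arrays were chosen after the data were seen. In Ca-free medium against control the count of 11193 probe sets was 5498 under quantile normalization, 5143 as deposited, and 5658 at a minimum signal of 300. It was 5886 at an adjusted p under 0.01, 4406 at a fold of at least 1.5 and 6520 with controls 3 and 4 only. The lower counts as deposited and at 300 come with fewer probe sets tested, 13600 and 14629 (the pseudocount and filter keep their size on the smaller deposited scale). For 20 pulses the count of 411 was 155 without the intensity trend, 717 with array weights, 227 with the replicate block and 63 at an adjusted p under 0.01. It was 181 at 1.5 times, 2160.0 with hybridization control scaling, 201 with controls 1 and 2 only, 786 with controls 3 and 4 only and 633 with Ca-free arrays 1 and 4 only. For Ca-free medium against 20 pulses the count of 9070 was 2801 under quantile normalization, 4682 as deposited, 5080.0 at a minimum of 300, and 3727 at an adjusted p under 0.01. It was 2829 at 1.5 times, 19960 with hybridization control scaling and 5890.0 with Ca-free arrays 2 and 3 only. The overlap of 233 was 91 without the trend, 389 with array weights, 139 with the replicate block and 42 at an adjusted p under 0.01. It was 73 at 1.5 times, 459 with hybridization control scaling, 146 with controls 1 and 2 only and 513 with controls 3 and 4 only. With the controls divided it was 221, 16, 14, 0, 6 and 76 when Ca-free medium had controls 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4. Fewer arrays per comparison are part of that construction, and 20 pulses had 0 calls where the overlap was 0. With the replicate block the counts of the Ca-free comparisons were 10957 and 8765, and of the named genes only Rbm5, Serpina3i, Eif2a and Tra2a lost a call, all after 20 pulses. Leaving out each array gave 9071 to 11143 probe sets for Ca-free medium against control, 110.0 to 414 for 20 pulses, 6103 to 8973 for the treatments and 67 to 231 shared, and 15 to 15, 4 to 7 and 16 to 18 lists.

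Lists past the threshold numbered 15 in Ca-free medium against control, but 3 under quantile normalization, 8 as deposited, 8 at a minimum of 300, 0 with an estimated correlation in camera of limma (where 13975 probe sets had an unadjusted p under 0.05) and 6 with hybridization control scaling. The 5 lists of 20 pulses became 1 under quantile normalization, 2 without the trend, 0 with an estimated correlation and 2 with hybridization control scaling. The 18 of the treatments became 7 under quantile normalization, 2 with an estimated correlation and 5 with hybridization control scaling. Lists whose test changed direction relative to all genes, with a pass in at least 1 of the settings, were, under quantile normalization, splicing in Ca-free medium (-0.0381), cytosolic ribosomal proteins (-0.00612) and proteasome subunits (-0.00517) after 20 pulses, whose medians stayed below 0. Epithelial junctions (-0.0894) and antioxidant genes (-0.0131) turned between the treatments. With hybridization control scaling, splicing (0.0762) and proteasome subunits (0.0668) turned after 20 pulses, and the genes Pou5f1 (-0.00434) and Krt8 (-0.198) in Ca-free medium. Under that scaling more medians, and genes without a call in either setting, changed sign. The other lists were mitochondrial ribosomal proteins after 20 pulses with controls 1 and 2 only (0.0588) and p53 targets with Ca-free arrays 2 and 3 only (-0.305). The difference in the 3' to 5' ratio was -0.205 with Actb alone in Ca-free medium against control, and 0.216 with Actb alone and -0.729 with Gapdh alone against 20 pulses. Of 3013 values of named genes under alternatives, 2806 stayed called in the same direction or stayed uncalled in either direction. Of 3222 values of lists 3035 did so, with the direction of the test and not of the median. For all other shifts the cause was not tested, and signal over background was not measured, since detection calls were not used here.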

Other observations

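The genes named in this part were chosen after their values were seen. Some lists did not pass as a whole in Ca-free medium against control while members passed under the trimmed mean, quantile and median scalings alike. The counts of list members that follow are calls with trimmed mean scaling only, where 2944 of all 27808 probe sets were higher and 8249 lower. Among 53 genes of calcium signalling, 3 rose and 17 fell (list median -0.15, but 0.19 under median scaling; adjusted p = 0.594). The plasma membrane Ca2+ pump Atp2b1 rose by 0.90 in Ca-free medium and by 0.82 after 20 pulses on the log2 scale, and a second probe set of the gene rose by 0.36 and 0.50. The calcineurin-dependent factor Nfatc2 fell by 1.48 in Ca-free medium. In glycolysis the glucose transporter Slc2a1 (log2 change 0.80) and Pgk1 (0.36) rose and Ldhb (-0.69) fell. Among 28 imprinted genes, 2 rose and 11 fell (list median -0.29, but 0.08 under median scaling; adjusted p = 0.577), with Gnas at 0.49, Dlk1 at -0.87 and Ndn at -0.82. Of 26 trophectoderm genes 3 rose and 7 fell, with the keratin Krt7 at 0.41 and the transcription factor Gata2 at -0.81.

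After 20 pulses a probe set of Sox17, a primitive endoderm factor, read 1289 ± 38.8 against 629.9 ± 72.2 in control (SD, n = 4; log2 change 1.00, adjusted p = 0.0269 by limma). The other probe set of the gene did not pass (0.34). Prdm14 (0.60), a pluripotency factor, the receptor Notch2 (0.54) and the kinetochore motor Cenpe (0.65) rose, and Fdps (-0.75), an enzyme of sterol synthesis, fell. Among lists of other cell types, cumulus and granulosa cell markers in Ca-free medium had 6 of 12 genes lower and 1 higher (list median -0.44, adjusted p = 0.199), with Inhba at -1.31 and Foxl2 at -0.97. Blood markers had 2 of 9 lower (adjusted p = 0.330). The raised signal of Nid1 after 20 pulses was in 1 probe set, while the other read 3990.0 ± 195 in control and 3959 ± 150.0 after 20 pulses.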
